A study of Mus musculus with 22 samples.

How the data were processed

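Total RNA of mouse cardiac fibroblast cultures was isolated with TRIzol and RNeasy columns, per the labels' protocols, and hybridised as 1-colour (Cy3) samples to Agilent mouse 8x60K arrays, 1 array per sample. The 22 arrays fall into 11 groups of 2 by the day and vector in their labels. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, which gave the deposited spot intensity after subtraction of background and detrending within the array, with no normalization between arrays. The files also hold the mean spot intensity and the median local background as scanned, per the file headers. A second deposited table holds 1 intensity per gene name and array, 34378 names in all. Its scale, centring and making are not stated beyond limma, which the submitters' processing notes name. Its ranks followed the median spot intensity minus local background of the same array (Spearman rho of at least 0.99997 on each array), its column medians lay between 198 and 206, and its distributions were nearly equal between arrays. It was used as an alternative only, and 27 of its names had no match among the scanner files' names.

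The main values were log2 of the processed intensity minus each array's 75th percentile over non-control spots. Control spots and spots marked as outliers by the scanner software were left out, and no spot was saturated. Spots of 1 probe were averaged on the log2 scale. A probe was kept when it was well above background on both arrays of at least 1 group, which kept 38813 probes and left out 16868. Of 55681 non-control probes 30186 were given a mouse gene symbol, 26056 through their accession, 3200 through a current symbol and 930 through a synonym, and 25495 were not named, 16194 of them probes of lincRNA regions. Probe coordinates are those of the array design, on the mm9 build. For genes with several kept probes (4719) the probe with the highest mean over all arrays was used, and 182 such genes had probes called in opposite directions in the averaged comparison, among the list members Mcam, Ppara and Tet3. This gave 18062 genes, of which 17923 had a value on every array and entered the list tests.

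One linear model with 11 group means was fitted over all 22 arrays with limma 3.58.1 (lmFit and eBayes, 11 residual and 1.66 prior degrees of freedom) in R 4.3.3. The comparisons were MGT minus lacZ on each of the 5 days, the mean of these, the change of this difference from day 3 to day 14, and lacZ day 3, lacZ day 14 and MGT day 14 minus day 0. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The test, the comparisons, the lists and the rule for named genes were set before the data were examined. The 23 lists were sarcomere, cardiac excitation and calcium handling, cardiac transcription factors, cardiac metabolism and hormones, skeletal muscle, fibroblast identity, extracellular matrix, smooth muscle and myofibroblast, cell cycle, interferon response, inflammatory response, splicing factors, oxidative phosphorylation, fatty acid oxidation, glycolysis, TGF-beta pathway, Notch pathway, chromatin regulators, endothelial, macrophage, epicardial and mesothelial, pericyte, and glial genes. Their shift was tested with camera at a preset correlation of 0.01, and again with an estimated correlation, for the averaged comparison, the change from day 3 to day 14 and lacZ day 3 minus day 0. Camera on the other comparisons was added after the data were examined. List members that were not measured included Hcn4, Prox1, Ckm, Ckmt2, Myf5, Cacng1, Col6a3, Dll4 and Cdh19.

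Named genes were Mef2c, Gata4 and Tbx5, the 10 largest rises and falls of the averaged comparison among genes with the same sign on all 5 days, the 4 largest of each direction per day, the 6 largest of each direction for the change over time and for each comparison with day 0, and up to 4 members of each list with the largest difference. All but the factors and list members had to pass the test, and clone and predicted gene names were left out. On simulated data with 200 of 17923 genes changed, the averaged comparison recovered 75% of them at a log2 difference of 0.5, 95.5% at 1 and 99% at 2. The change over time recovered 3.5%, 59.5% and 84.5%, and day 7 recovered 33%, 73% and 91%. False calls made up 7.98%, 6.83% and 5.26% of the calls of the averaged comparison, each above the threshold of 0.05. They made up 0%, 3.25% and 3.43% for the change over time, and 0%, 3.95% and 7.14% for day 7. Far more genes were called in the real data (11544 for the averaged comparison), so these shares need not hold there. The simulation also gave each gene the same spread in all 11 groups. In the real data the median absolute log2 difference between replicates was 0.0583 in day 3 lacZ and 0.264 in day 14 lacZ. The shares for single days and for the change over time need not hold for this reason too. Camera called the 1 list shifted in the simulation and 0 others. The simulated genes varied independently, so this does not test for false list calls that come from correlated genes.

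Alternatives run were quantile normalization, normexp background correction with an offset of 50 on the mean and local background intensities, the deposited table, no filter on dim probes, only the 24163 probes well above background on every array, outlier spots kept, the mean of a gene's probes, an eBayes trend with robust estimation, only the arrays of the comparison, the replicate number as a block, a stricter threshold, fry, and each array left out in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Days 3 and 5 lay on slide 1 and days 7 and 10 on slide 2. Day 0 and day 14 lacZ lay on slide 3 and day 14 MGT on slide 4. Slides 1 and 2 were scanned on 1 date and slides 3 and 4 on another. Replicates correlated with r between 0.985 (day 14 lacZ) and 0.998 across genes, with 1 probe per gene. The median absolute log2 difference between the 2 arrays of a group was 0.0583 to 0.264.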

Results

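RNA was profiled on Agilent 1-colour mouse arrays from cardiac fibroblasts (CF) of CD1 mice with the aMHC-GFP genotype, a green fluorescent reporter driven by the promoter of the cardiac myosin gene Myh6. The fibroblasts were infected with a retrovirus carrying Mef2c, Gata4 and Tbx5 on 1 polycistronic transcript (MGT), 3 cardiac transcription factors that convert fibroblasts into induced cardiomyocytes. The control retrovirus carried lacZ, the bacterial beta-galactosidase gene. Untransduced fibroblasts were taken at day 0, and lacZ and MGT cultures at days 3, 5, 7, 10 and 14. The 11 groups had 2 arrays each, 22 in all. The series design states that the arrays were made for comparison with single-cell RNA-seq of induced cardiomyocytes, which was not used here. On each array 59305 non-control spots were read, of which 48.4% (second day 14 lacZ array) to 71.0% (first day 14 MGT array) were well above background. The 75th percentile of the processed signal lay between 1285 and 2124 except on the second day 14 lacZ array, where it was 729. The labels do not say that replicates came from separate cultures or animals, so each p-value measures only the spread between these samples, which may be technical, and the number of arrays limits the precision. Levels are log2 values relative to each array's 75th percentile and differences are log2 differences with the standard error (SE) of the limma fit. Adjusted p-values are Benjamini-Hochberg values from that fit.

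The transgene factors were examined in every group, since they bear on the labels. Mef2c RNA was 4.21 higher with MGT than with lacZ on average over days 3 to 14 (SE 0.23, adjusted p = 2.41e-09, 10 arrays each). It was higher on all 5 days. Its difference was 6.78 at day 3, 4.54 at day 5, 3.86 at day 7, 3.59 at day 10 and 2.26 at day 14. The 2 day 5 lacZ arrays lay apart (-1.74 and -4.13), and the day 5 difference was 5.73 without the first and 3.34 without the second. The Mef2c level with MGT was 2.90 ± 0.08 (SD, n = 2) at day 3 and 0.00 ± 0.09 at day 14, against -3.88 ± 0.01 and -2.26 ± 0.05 with lacZ. The probe reads Mef2c coding sequence from position 1104 of the transcript, on chromosome 13 from 83772788 to 83775025 in the mm9 build given in the files. Gata4 differed by 0.35 on average (SE 0.04, adjusted p = 2.40e-06) and passed the test as higher at days 7, 10 and 14. The Gata4 call at day 14 (0.37, adjusted p = 0.0026) was lost with normexp background correction (0.18, adjusted p = 0.163) and with the deposited table (0.23, adjusted p = 0.0956). With only the arrays of the comparison both the day 10 call (adjusted p = 0.0941) and the day 14 call (adjusted p = 0.085) were lost, and over all settings run the adjusted p at day 14 lay between 0.000265 and 0.163. Gata4 did not pass at day 3 (0.22, adjusted p = 0.0653) or day 5 (0.18, adjusted p = 0.118), where the adjusted p lay between 0.0153 and 0.318 and between 0.0213 and 0.591 over the settings. Tbx5 differed by 0.08 on average (SE 0.11, adjusted p = 0.567), a mean over days with opposite signs. Its difference was 0.39, 0.55, 0.21, -0.15 and -0.61 at days 3, 5, 7, 10 and 14 (adjusted p = 0.284, 0.0992, 0.569, 0.659 and 0.0574). Under the 15 other settings it passed as higher in 3 at day 5, with adjusted p down to 0.00609, and in 1 at day 3 (adjusted p = 0.027), and as lower in 5 at day 14, among them normexp background correction (-0.78, adjusted p = 0.00237). It also passed as higher averaged within slide 1 (0.47, adjusted p = 0.0422). The Gata4 probe lies on chromosome 14 from 63817858 to 63817917 and starts at position 3227 of the transcript. The Tbx5 probe lies on chromosome 5 from 120334087 to 120334146 and starts at position 2800. Which part of each transcript the vector carries is not given in the sources used here. These Gata4 and Tbx5 values therefore do not check for the vector.

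The comparison of MGT with lacZ cultures averaged over the 5 days asks what the 3 factors change against a control virus of the same day. Sln, which encodes sarcolipin, a regulator of the calcium pump of the sarcoplasmic reticulum, was 11.28 higher with MGT (SE 0.13) and was measured above background on 10 MGT but only 5 lacZ arrays. Myl7, the atrial myosin regulatory light chain, was 9.65 higher (SE 0.10), and Actc1, cardiac alpha-actin, was 8.69 higher (SE 0.05, adjusted p = 8.99e-19). Myom2, an M-band protein of the sarcomere, was 8.37 higher. The titin gene Ttn, Smpx, Csrp3 and Sphkap, which encodes an anchoring protein for protein kinase A, also passed as higher but were above background on 2 of the 10 lacZ arrays, and Myl1 on 1. The sizes of these 5 rises were thus not measured, and the fitted values depended on the settings, from 4.58 to 10.34 for Smpx, 5.97 to 10.96 for Myl1 and 5.73 to 10.08 for Ttn. Wif1, a secreted inhibitor of Wnt signals, was below background on all 10 lacZ arrays and was at least 166-fold higher with MGT. A difference between 2 sets of arrays is given as a bound for a gene well above background on no array of 1 set, the brighter group's mean over the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. These bounds hold for the main settings only. Under other settings some fitted log2 differences were smaller than the bound, down to 7.72 for Myl1 at day 10. They went down to 6.24 for Ttn at day 7 and to 1.995 for Rpl10l in lacZ day 3 minus day 0. With some arrays of a set at background, or for a change of a difference, the fitted value is given. It rests in part on signals at background. Among the falls named, Smoc1, a secreted matricellular protein, fell by 3.60 (SE 0.07), the Wnt antagonist gene Sfrp1 by 3.34, Plac8 by 3.24 and the peptidase gene Dpp4 by 3.21, measured on all 20 arrays. The RNA helicase gene Ddx4 of the germ line (-4.08, SE 0.16), Ldb2, a LIM domain-binding factor (-3.76), Cyp4b1 (-3.38), the neuropeptide gene Nts (-3.32), Pcdh10 (-3.30) and the endothelial transcription factor gene Sox18 (-3.30) also fell. MGT arrays above background numbered 7 for Ddx4, 6 for Cyp4b1 and Pcdh10, 4 for Nts and 2 for Ldb2 and Sox18, so the order of these falls was not measured.

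Of 29 measured sarcomere genes 28 rose with MGT and 0 fell, with a median of 4.59 (camera adjusted p = 1.38e-24), and 28 rose adjusted over the list alone. Of 26 genes of cardiac excitation and calcium handling 22 rose and 2 fell (median 2.59, adjusted p = 2.73e-14), with 22 and 2 adjusted over the list alone. Beside Sln these included Ryr2, the calcium release channel (6.996, SE 0.13), Casq2, calsequestrin (6.22, SE 0.05), and Trdn, triadin (5.10, SE 0.12), with Ryr2 above background on 2 lacZ arrays and Trdn on 8. Of 13 genes of cardiac metabolism and hormones 12 rose and 0 fell, as many adjusted over the list alone (median 2.24, adjusted p = 3.89e-11), among them Mb, myoglobin (7.83, SE 0.16, above background on 3 lacZ arrays), and Slc2a4, the insulin-responsive glucose transporter (3.33, SE 0.05). Of 23 genes of fatty acid oxidation 11 rose and 4 fell, with 11 and 4 adjusted over the list alone (median 0.09, adjusted p = 0.00435, but adjusted p = 0.0716 with an estimated correlation), led by the thiolase Acaa2 (1.77, SE 0.05) and Pdk4 (1.68, SE 0.07), which limits pyruvate oxidation. Skeletal muscle genes also moved: 13 of 20 rose and 1 fell, as many adjusted over the list alone (median 0.50, adjusted p = 1.42e-05), led by Tnnt3, fast skeletal troponin T (5.34, SE 0.06), and the myosin heavy chain gene Myh8 (5.12, SE 0.08). The 17 measured cardiac transcription factor genes other than the 3 delivered ones went both ways, with 4 higher and 9 lower (5 and 9 adjusted over the list alone, adjusted p = 0.848). Their mean was 0.28 and their median -0.15. The 4 that rose were Esrrg (3.79, SE 0.16, above background on 2 lacZ arrays), Hopx (3.77, SE 0.07), Myocd (1.52, SE 0.09) and Ankrd1 (1.35, SE 0.05).

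Of 26 fibroblast identity genes 21 fell and 3 rose, with 21 and 3 adjusted over the list alone (median -1.15, camera adjusted p = 5.73e-07). The small proteoglycan gene Lum fell by 3.02 (SE 0.05) and Dpt, dermatopontin, by 2.51 (SE 0.05). Of 27 extracellular matrix genes 22 fell and 4 rose (23 and 4 adjusted over the list alone, median -0.53, adjusted p = 0.000155, but adjusted p = 0.277 with an estimated correlation). Col3a1 fell by 1.84 (SE 0.06) and the protease inhibitor gene Timp3 by 1.48 (SE 0.06), while Col12a1 rose by 1.46 (SE 0.04). Of 28 interferon response genes 25 fell and 0 rose (26 and 0 adjusted over the list alone, median -0.56, adjusted p = 8.25e-06, but adjusted p = 0.464 with an estimated correlation), among them the nucleic acid sensor Zbp1 (-1.45, SE 0.06) and Ifit3 (-1.29, SE 0.11). Of 29 inflammatory genes 19 fell and 5 rose (21 and 5 adjusted over the list alone, median -0.52, adjusted p = 0.0156, but adjusted p = 0.596 with an estimated correlation), led by the stromelysin Mmp3 (-2.83, SE 0.13) and the chemokine Cxcl5 (-2.64, SE 0.11). Of 40 cell cycle genes 25 fell and 4 rose, as many adjusted over the list alone (median -0.27, adjusted p = 0.0307, but adjusted p = 0.878 with an estimated correlation), with Mybl2 down by 0.57 (SE 0.06) and the centromere histone gene Cenpa up by 1.503 (SE 0.06). Of 14 endothelial markers 11 fell and 1 rose, as many adjusted over the list alone (median -1.48, adjusted p = 0.0157, but adjusted p = 0.287 with an estimated correlation), and the tight junction gene Cldn5 fell by 2.95 (SE 0.12), above background on 2 MGT and 7 lacZ arrays. The sarcomere, excitation, cardiac metabolism, skeletal muscle and fibroblast identity shifts held with an estimated correlation, with adjusted p between 0.000103 and 0.042.

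Camera called no shift for the other lists, whose counts of higher and lower members are given with those adjusted over the list alone in brackets. They were 4 and 6 of 12 smooth muscle and myofibroblast genes (5 and 6), 2 and 16 of 28 splicing factors (2 and 16), 8 and 5 of 37 oxidative phosphorylation genes (8 and 5), and 4 and 9 of 18 glycolysis genes (4 and 10). They were 5 and 13 of 19 TGF-beta pathway genes (5 and 13), 3 and 9 of 13 Notch pathway genes (3 and 9), and 5 and 7 of 20 chromatin regulators (5 and 7). Among markers of other cell types they were 0 and 2 of 20 macrophage (0 and 2), 5 and 6 of 11 epicardial and mesothelial (5 and 6), 3 and 3 of 6 pericyte (3 and 3), and 3 and 2 of 7 glial genes (3 and 2). The adjusted p of these shifts ran from 0.0899 to 0.895. The mean and the median differed in sign for TGF-beta pathway genes, chromatin regulators and glial markers.

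Over all 18061 genes tested, 11544 differed on average between MGT and lacZ, 4198 higher and 7346 lower (36.4% higher), and 1985 of them by at least 1 on the log2 scale, where the direction turned (1090 higher and 895 lower, 54.9% higher). The median of all genes was -0.09. With the 75th percentile taken over probes well above background on every array, a scaling chosen after seeing the data, 46.5% of the 11130 calls were higher. Each group lay on 1 slide, and lacZ and MGT shared a slide at days 3 to 10, so those differences are within slides. Averaged over days 3 to 10 alone 10652 genes differed, within slide 1 (days 3 and 5) 8278 and within slide 2 (days 7 and 10) 9070. The median shift was 3.56 in slide 1 and 4.93 in slide 2 for sarcomere genes, 1.48 and 3.02 for excitation genes, 1.56 and 2.56 for cardiac metabolism and hormones, and 0.41 and 0.57 for skeletal muscle. It was -0.79 and -1.22 for fibroblast identity, -0.42 and -0.50 for matrix, -1.27 and -0.36 for interferon, -0.47 and -0.56 for inflammatory, -1.13 and -1.78 for endothelial, 0.09 and 0.13 for fatty acid oxidation, and -0.30 and -0.19 for cell cycle genes. All of these were called within both slides except cell cycle, which was not called within slide 2 (adjusted p = 0.329). Over all days the cell cycle call was lost without the second day 14 lacZ array (adjusted p = 0.0607) or the first day 14 MGT array (0.0508). It was also lost with normexp background correction (0.0552), the deposited table (0.0621), no filter on dim probes (0.057) and probes above background on every array (0.0725). The endothelial call was lost over probes above background on every array (median -0.45, adjusted p = 0.201).

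The same contrast was read on each day to follow the change over time. Sarcomere genes were higher by a mean of 2.93 at day 3, 4.49 at day 5, 5.22 at day 7, 5.61 at day 10 and 5.70 at day 14, and 24, 26, 27, 28 and 26 of the 29 rose (24, 27, 28, 28 and 26 adjusted over the list alone). Fibroblast identity genes were lower by -0.34, -1.11, -1.29, -1.15 and -1.23 on the same days, and 13, 20, 22, 21 and 21 of the 26 fell (14, 21, 22, 22 and 22 adjusted over the list alone), while 5, 2, 2, 2 and 2 rose. The day 3 call (camera adjusted p = 0.0476) was lost with an estimated correlation (adjusted p = 0.458 with an estimated correlation), and those of days 5 to 14 were kept (adjusted p from 0.0109 to 0.0231). From day 3 to day 14, on different slides, the mean sarcomere level went from 1.39 to 2.80 with MGT and from -1.55 to -2.90 with lacZ. That of fibroblast identity genes went from 2.72 to 2.33 with MGT and from 3.05 to 3.56 with lacZ. The widening of both differences thus came in part from the lacZ cultures. At day 3 the rises named were Myl7 (8.15), Sphkap (at least 103-fold), Scg2, a granin of secretory vesicles (7.25, SE 0.14), and Abi3bp (7.08). The falls named were bounds with no measured order, Egr4 (at least 6.07-fold), Hfm1 (at least 5.50-fold), Cyp2j5 (at least 3.94-fold) and Tmprss9 (at least 5.39-fold). At day 5 Sln rose at least 2265-fold, Ttn at least 205-fold and Smpx at least 133-fold, and Actc1 by 9.69. Ddx4 fell at least 18.6-fold, Kcnc2 at least 8.73-fold, Olfr982 at least 7.17-fold and Synpr at least 5.52-fold. At day 7 the rises named were Sln (11.68), Ttn (at least 686-fold), Smpx (at least 498-fold) and Myl1 (at least 498-fold). The falls named, again bounds with no measured order, were Ldb2 (at least 8.18-fold), Nts (at least 7.80-fold), Sox18 (at least 4.84-fold) and Fmo1 (at least 4.76-fold).

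At day 10 Sln rose at least 8303-fold and Myl1 at least 1453-fold, and Myl7 (10.26) and Actc1 (10.21) were measured in both groups. Dlk1, a non-canonical Notch ligand, fell by 5.20 (SE 0.16), Ucn2 at least 7.38-fold (adjusted p = 0.0521 with only the arrays of the comparison), Gngt1 at least 7.37-fold and Olfr102 at least 5.78-fold. At day 14 Sln was 12.24 and Myl7 11.12 higher, each above background on 1 of 2 lacZ arrays, Actc1 was 10.76 higher (SE 0.11) and Myl1 at least 913-fold. Galntl5, Ush1c and Albfm1, lower at least 19.5-, 34.3- and 16.2-fold, were above background on both day 14 lacZ arrays and, among all other arrays, on 1 day 0 array of the same slide (Galntl5 and Ush1c) or none (Albfm1). The Albfm1 call was lost with only the arrays of the comparison (adjusted p = 0.058). Sox18 was lower at least 11.7-fold, above background on 1 of 2 lacZ arrays. Per day 5494, 6876, 6734, 7105 and 8591 genes differed, of which 2230, 2919, 2687, 2742 and 3296 were higher and 3264, 3957, 4047, 4363 and 5295 lower. Across 18061 genes 1172 were higher on all 5 days, against 1.49 for independent lists, and 1366 were lower, against 11.3. The fit used 1 spread per gene for all days, so the calls of different days are not independent and this excess was not tested. Across genes, which are not independent replicates, differences of adjacent days correlated with Pearson r between 0.761 and 0.876 (Spearman rho 0.658 to 0.743), and those of days 3 and 14 with r = 0.601 (rho = 0.395), without a test. The day 14 lacZ and MGT arrays lay on different slides, so slide and vector cannot be told apart there. The share of higher calls at day 14 was 38.4% but 49.6% with quantile normalization, 49.5% with the deposited table, 26.8% with normexp background correction and 49.3% with the percentile over detected probes. With that percentile 49.6%, 49.9%, 48.7% and 46.8% were higher at days 3, 5, 7 and 10. With the 75th percentile over all probes, more of the genes that differed by at least 1 on the log2 scale were higher than lower on each day (793 against 667 at day 3, 1300 against 1288 at day 14). With only the 4 arrays of each contrast the order of the days turned, with 7367, 7096, 5766, 3286 and 2699 genes at days 3, 5, 7, 10 and 14.

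**Figure D1:**
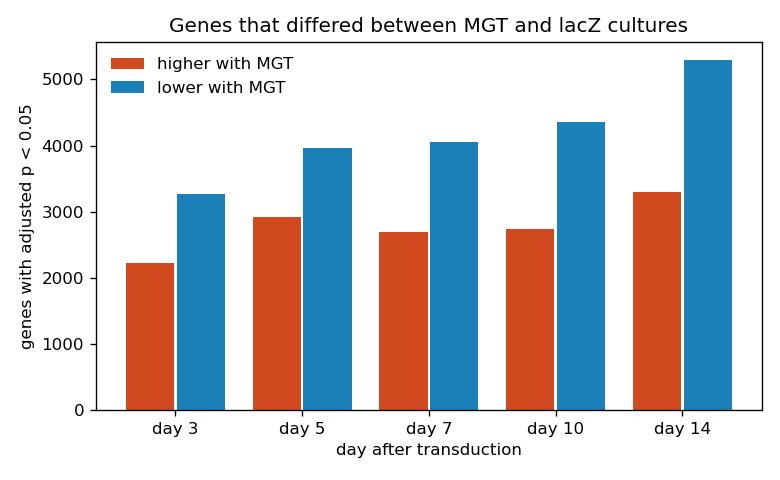
Number of genes higher (red) and lower (blue) with MGT than with lacZ on each day, at an adjusted p under 0.05 (vertical axis, genes; horizontal axis, day after transduction). Lower genes outnumbered higher ones on each day, from 3264 against 2230 at day 3 to 5295 against 3296 at day 14, where the split was near even under 3 of the 4 other scalings, and with the percentile over detected probes it was near even at days 3 to 7 too (48.7% to 49.9% higher).

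Whether the effect of MGT differed between the beginning and the end of the course was tested as the change of the MGT minus lacZ difference from day 3 to day 14. Of the 12 genes named, 3 were above background on all 8 arrays of this contrast. Myh6, the alpha myosin heavy chain, increased by 10.30 (SE 0.20, adjusted p = 5.99e-12). Its level at day 3 was 2.31 ± 0.15 with MGT and 2.16 ± 0.02 with lacZ (SD, n = 2 each), close to the day 0 level of 2.21 ± 0.04. At day 14 it was 7.17 ± 0.12 with MGT and -3.28 ± 0.31 with lacZ. The difference of Scg2 decreased (-5.36, SE 0.19). Its level went from 5.33 ± 0.04 to 7.21 ± 0.09 with MGT and from -1.93 ± 0.03 to 5.31 ± 0.05 with lacZ. Gdpd2 changed from higher to lower with MGT (-5.08, SE 0.14). The other 9 passed the test, but their fitted values rest in part on signals at background and give no order. They were 6.999 for the Z-disc gene Actn2, 7.57 for the myosin gene Myh7b and 6.82 for Mb (each above background on 6 of 8 arrays), 6.85 for Myl1 (5 of 8) and -5.37 for Lrat (4 of 8). Iqsec3 (7.36, and 3.39 to 7.74 over the settings) was above background on the 2 day 14 MGT arrays alone. Galntl5, Ush1c and Albfm1 (-6.38, -6.22 and -6.04) were above background on the 2 day 14 lacZ arrays alone, and with day 10 in place of day 14 their calls were lost (-0.60, -0.68 and -0.58, adjusted p = 0.789, 0.845 and 0.768). The difference decreased for Mef2c by -4.52 (SE 0.73, adjusted p = 0.000622).

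Among the lists the increase was in sarcomere (22 of 29 rose and 1 fell, median 2.64, camera adjusted p = 8.95e-18; 23 and 1 adjusted over the list alone), excitation and calcium handling (19 of 26 and 0, median 1.42, adjusted p = 4.79e-15; 21 and 0) and cardiac metabolism and hormones (8 of 13 and 1, median 1.34, adjusted p = 6.84e-06, adjusted p = 0.0956 with an estimated correlation; 8 and 1). Interferon response genes increased too, 23 of 28 with 1 decreased (median 1.15, adjusted p = 4.84e-12, adjusted p = 0.188 with an estimated correlation; 25 and 1 adjusted over the list alone). Their mean difference was -1.02 at day 3, -1.58 at day 5, -0.92 at day 7, 0.12 at day 10 and 0.27 at day 14, with adjusted p = 0.264, 0.161 and 0.278 with an estimated correlation at days 3, 5 and 7. The difference of the antiviral gene Mx2 was -2.00 at day 3 and 0.56 at day 14 and that of the chemokine Cxcl10 -1.91 and 0.97. Skeletal muscle (5 of 20 and 1, median 0.74, adjusted p = 0.0226; 6 and 1) and glial genes (2 of 7 and 0, median 0.60, adjusted p = 0.0228; 3 and 0) increased, both with adjusted p = 0.0956 with an estimated correlation and both with a median below 0 under normexp background correction (-0.31 and -0.17). The decrease was in fibroblast identity (18 of 26 fell and 1 rose, median -0.78, adjusted p = 1.22e-08; 18 and 1 adjusted over the list alone), extracellular matrix (17 of 27 and 1, median -0.69, adjusted p = 6.56e-06, adjusted p = 0.178 with an estimated correlation; 17 and 3) and macrophage markers (2 of 20 and 0, median -0.80, adjusted p = 0.0226, adjusted p = 0.92 with an estimated correlation; 2 and 0). In all, the difference changed for 4978 genes, 2223 up and 2755 down. Such a change can come from either vector, as for sarcomere genes, whose mean level with lacZ fell from -1.55 to -2.90. With day 10, where both vectors share a slide, in place of day 14 (chosen after seeing the data) 2861 genes changed and the skeletal muscle and glial calls were lost (adjusted p = 0.164 and 0.654). The skeletal muscle call was also lost without the first day 14 lacZ array (adjusted p = 0.127), with normexp (0.396) and over probes above background on every array (0.0788). The glial call was lost without either day 14 lacZ array (0.0667 and 0.0532), with quantile normalization (0.0672), with the deposited table (0.195) and with normexp (0.306). The macrophage call was lost without the second day 14 lacZ array (0.165) or the first day 14 MGT array (0.0567), with normexp (0.169), with no filter on dim probes (0.101), over probes above background on every array (0.0648) and with fry (0.138). The share that went up was 44.7%, but 56.4% with quantile normalization, 55.9% with the deposited table and 33.2% with normexp background correction.

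**Figure D2:**
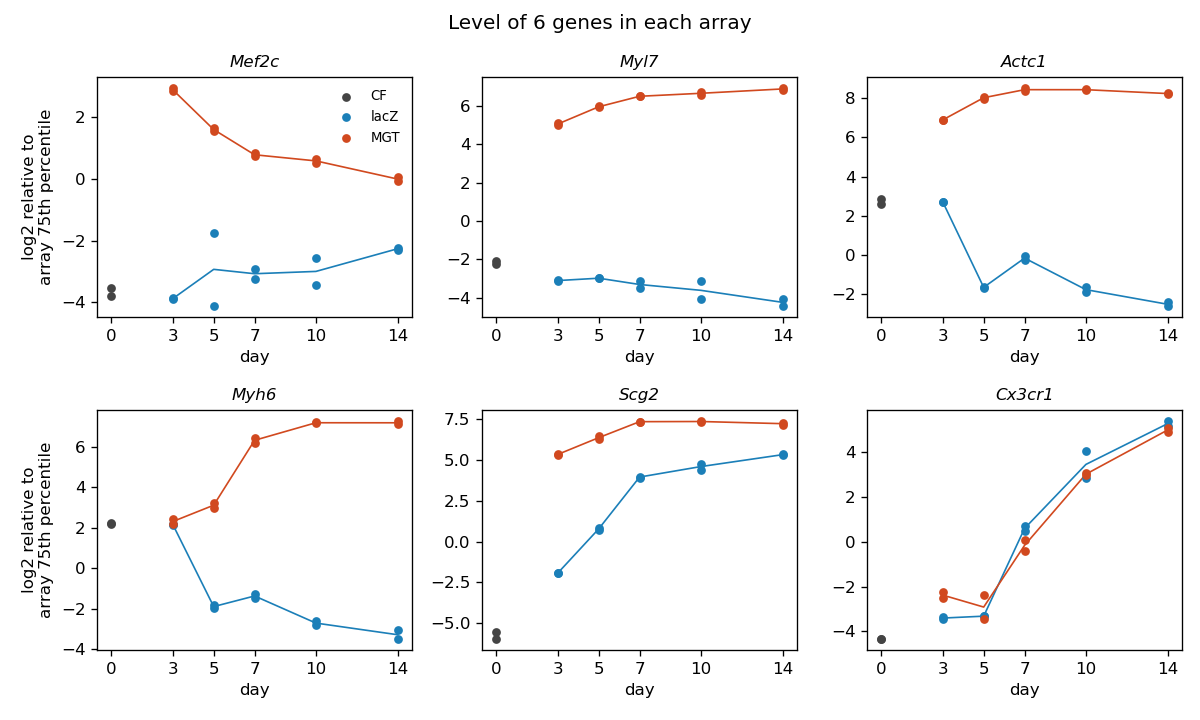
Level of 6 genes on each array (points) with the group means joined by lines, as log2 relative to the array's 75th percentile (vertical axis) by day (horizontal axis), for day 0 fibroblasts, lacZ and MGT. Myh6 stood near 2.21 in all 6 arrays of days 0 and 3 and reached 7.17 with MGT and -3.28 with lacZ at day 14, while the Mef2c difference narrowed from 6.78 to 2.26.

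The lacZ cultures at day 3 were compared with day 0 fibroblasts, which shows what the control virus and the first days of culture changed. Ccn5, a matricellular growth regulator, rose by 7.39 (SE 0.11, adjusted p = 2.05e-13), Hsd11b1, which makes active glucocorticoid, by 6.004 (SE 0.10), and Scel by 6.58 (SE 0.12). Mrap2 rose at least 42.8-fold, Fbxw18 at least 29.1-fold and Rpl10l at least 29.0-fold. The cytokine genes Il1b and Tslp fell by 6.80 (SE 0.33) and 6.22 (SE 0.16), Penk, the enkephalin precursor, by 6.16 (SE 0.44), Sprr2h by 8.82 (above background on 1 of 2 day 3 arrays), Sprr2e at least 32.3-fold and Reln at least 20.4-fold. Inflammatory genes were lower as a group, with 23 of 29 fallen and 2 risen (25 and 2 adjusted over the list alone, median -1.44, camera adjusted p = 2.22e-07, adjusted p = 0.468 with an estimated correlation). Of 28 splicing factor genes 26 fell and 0 rose, as many adjusted over the list alone (median -0.65, adjusted p = 2.22e-07, adjusted p = 0.0196 with an estimated correlation), led by Srsf3 (-1.25, SE 0.06). Of 28 interferon response genes 13 fell and 1 rose, as many adjusted over the list alone (median -0.35, adjusted p = 0.0412, adjusted p = 0.725 with an estimated correlation), led by Rsad2 (-2.66, SE 0.36). Of 20 chromatin regulators 14 fell and 4 rose, as many adjusted over the list alone (median -0.36, adjusted p = 0.0465, adjusted p = 0.534 with an estimated correlation), led by Uhrf1 (-1.27, SE 0.18) and the DNA methyltransferase Dnmt1 (-1.20, SE 0.18). Of 12 smooth muscle and myofibroblast genes 8 rose and 1 fell, as many adjusted over the list alone (median 0.93, adjusted p = 0.00446, adjusted p = 0.725 with an estimated correlation), with calponin, Cnn1, up by 3.93 (SE 0.09) and Myh11 at least 9.12-fold. Of 27 extracellular matrix genes 13 rose and 7 fell (14 and 7 adjusted over the list alone, median 0.36, adjusted p = 0.049, adjusted p = 0.725 with an estimated correlation), with Col11a1 up by 5.08 (SE 0.08) and Tnc, tenascin C, down by 2.85 (SE 0.19). Over all genes 10434 differed, 5200 higher and 5234 lower. The matrix, interferon and chromatin calls were lost without the second day 0 array (adjusted p = 0.0758, 0.0537 and 0.0591) and with quantile normalization (0.0529, 0.0529 and 0.0591), and 3 lists were called under each. The matrix and chromatin calls were also lost without the second day 3 lacZ array (0.114 and 0.0637) and with the percentile over detected probes (both 0.0509), and the interferon and chromatin calls over probes above background on every array (0.0563 and 0.0581). The day 0 and day 3 arrays lay on different slides, so slide and culture cannot be told apart.

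From day 0 to day 14 in lacZ cultures, where both groups lay on the same slide, Scg2 rose at least 1849-fold, Nxpe5 at least 257-fold, Ambp at least 97.5-fold and Mrap2 at least 70.8-fold, and Ccn5 rose by 8.91 (SE 0.11). Cx3cr1, the fractalkine receptor of macrophages and monocytes, rose by 9.63 (SE 0.35, adjusted p = 5.28e-11), from -4.35 to 5.28 ± 0.16 (SD, n = 2). The chemokine genes Cxcl3 and Cxcl5 changed by -10.07 (above background on 1 of 2 day 14 arrays) and -9.33 (SE 0.24) and Tslp by -8.59 (SE 0.16). Falls that are bounds were Sprr2h at least 210-fold, Serpinb2 at least 191-fold and S100a9 at least 115-fold. Of 20 macrophage markers 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 2.27), and the complement genes C1qc and C1qa rose by 5.72 (SE 0.44) and 5.06 (SE 0.40). Camera, run on this comparison after the data were examined, gave adjusted p = 0.000197 for macrophage markers and adjusted p = 0.558 with an estimated correlation. Of 14 endothelial markers 11 fell and 1 rose, as many adjusted over the list alone (median -2.43), among them Cldn5 (-3.49, SE 0.27). Interferon response genes fell in 27 of 28 cases and rose in 0, splicing factors in 27 of 28 and 0, inflammatory genes in 24 of 29 and 3 (24 and 4 adjusted over the list alone), and cell cycle genes in 28 of 40 and 3. Extracellular matrix genes rose in 20 of 27 cases and fell in 7, and glycolysis genes rose in 14 of 18 and fell in 1. Sarcomere genes fell in 18 of 29 cases and rose in 9, with Myh6 down by 5.49 (SE 0.14), Actc1 by 5.26 (SE 0.11) and Myl3 by 5.08 (SE 0.18). Where no other count is given, that adjusted over the list alone was the same. In all 12448 genes differed, 6417 higher and 6031 lower.

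MGT cultures at day 14 were compared with the day 0 fibroblasts as the start and end of the course. Scg2 rose at least 6869-fold, Tnnt3 at least 641-fold, Armh4 at least 469-fold and Mal at least 453-fold, Sln by 10.40 (SE 0.30) and Myl1 by 10.23 (SE 0.39, above background on 1 of 2 day 0 arrays). The chemokine genes Cxcl5 and Cxcl3 changed by -12.01 (SE 0.24) and -8.85 (SE 0.45). Falls that are bounds were Sprr2h at least 900-fold, the calprotectin subunit S100a9 at least 493-fold, Il1a at least 252-fold and Csf3 at least 139-fold. Of 29 sarcomere genes 25 rose and 2 fell, of 26 excitation genes 23 and 2, and of 13 genes of cardiac metabolism and hormones 11 and 2, each the same adjusted over the list alone. Fibroblast identity genes fell in 15 of 26 cases and rose in 7 (16 and 7 adjusted over the list alone), macrophage markers rose in 18 of 20 and fell in 1, and endothelial markers fell in 12 of 14 and rose in 1, both the same adjusted over the list alone. In all 12736 genes differed, 5972 higher and 6764 lower. The 2 day 14 groups shared the day 0 arrays, and 4610 genes were higher in both than at day 0, against 2121.7 for independent lists. There were 5020 lower in both, against 2258.5. The correlation of the 2 sets of differences across genes was 0.758, against 0.503 simulated for unchanged groups, and the covariance 1.56 against 0.0375. Part of this excess may come from the shared day 0 arrays and, for the counts, from the 1 spread per gene used in the fit. The day 14 MGT arrays lay on a slide of their own, so slide and group cannot be told apart.

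**Figure D3:**
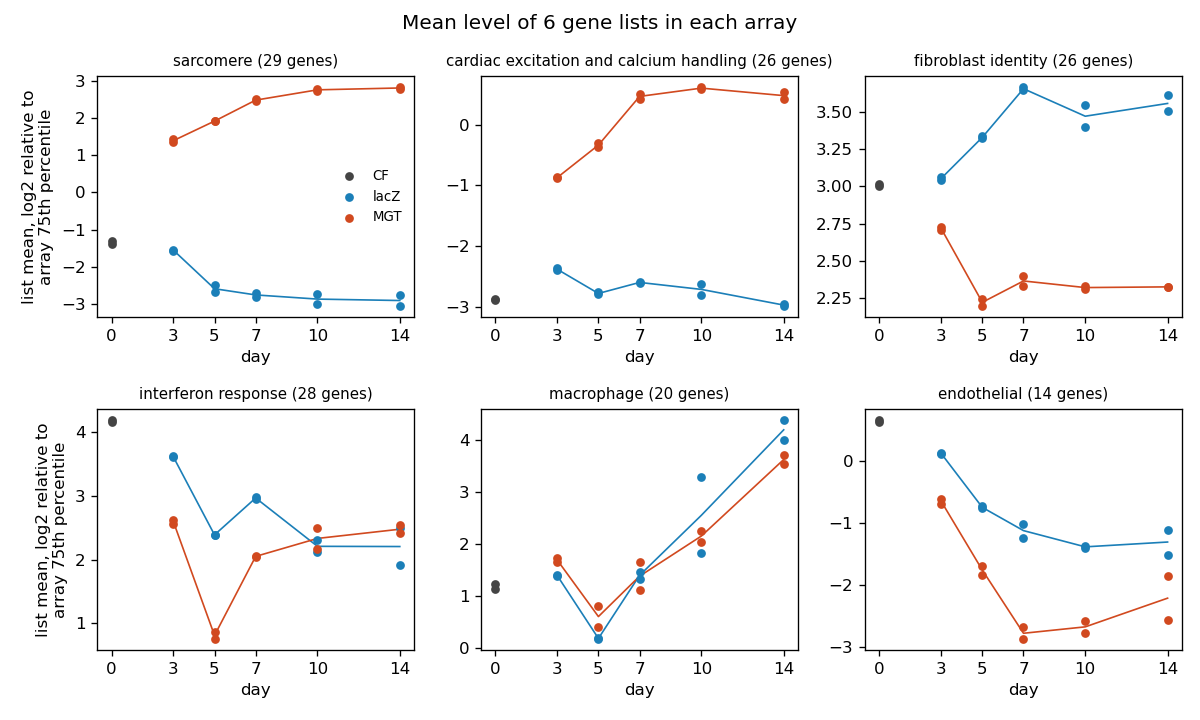
Mean log2 level of 6 gene lists on each array (points, relative to the array's 75th percentile, vertical axis) by day (horizontal axis), with group means joined by lines. Sarcomere genes separated between MGT and lacZ from day 3 on (2.93 to 5.70). Against other genes, camera called the interferon difference up to day 7 only at the preset correlation (adjusted p = 0.264, 0.161 and 0.278 with an estimated correlation). The same held for the macrophage rise in lacZ cultures towards day 14 (camera adjusted p = 0.558 with an estimated correlation). Fry, which does not compare a list with other genes, called these shifts too.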

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

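The tests on macrophage markers, interferon response genes, the day 14 count and lincRNA regions were chosen only after the result was seen, while the change over time and the 2 tests on other splits of the arrays were planned. Random splits of the arrays within each day into 2 sets, 100 with the real one, gave at most 5991 genes. The real split gave 11544, so 1 of the 100 reached that count. Most other splits mix MGT and lacZ arrays within a set, which widens the spread they are tested against. They therefore do not exclude chance for the number of genes, such as a difference between single cultures if the replicates are technical. For the number of lists 13 of the 100 splits, the real one included, gave as many as the real split (11 lists), up to 13. In the others that did so, MGT arrays were divided unequally between the 2 sets. Those splits thus held part of the MGT difference. Splits with 5 MGT arrays in the first set gave at most 8 lists. The splits therefore do not measure chance for the number of lists and cannot exclude it.

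The change of the MGT minus lacZ difference from day 3 to day 14, tested as an interaction, passed for 4978 genes. Above background on all 8 arrays were Myh6 (10.301), Scg2 (-5.36) and Gdpd2 (-5.082). The values of the other genes named rest in part on signals at background and give no order. They were 7.574 for Myh7b, 6.999 for Actn2, 6.855 for Myl1, 6.822 for Mb and -5.369 for Lrat, 7.364 for Iqsec3, above background on the day 14 MGT arrays alone, and -6.376 for Galntl5, -6.222 for Ush1c and -6.037 for Albfm1, above background on the day 14 lacZ arrays alone. The median change was 2.636 for sarcomere, 1.421 for excitation and calcium handling, 1.337 for cardiac metabolism and hormones, 0.743 for skeletal muscle, -0.779 for fibroblast identity, -0.692 for extracellular matrix, 1.153 for interferon response, -0.802 for macrophage and 0.599 for glial genes. Of these 9 calls 6 were lost with an estimated correlation, at adjusted p = 0.0956 for cardiac metabolism, skeletal muscle and glial, 0.178 for matrix, 0.188 for interferon and 0.92 for macrophage genes.

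Probes of lincRNA regions, which carry no gene name and enter no comparison of the report, were tested with the same model in a separate fit. That fit also held the other kept probes with no gene symbol, and p-values were adjusted over both kinds. Of 9199 kept lincRNA region probes 3390 differed on average between MGT and lacZ, 1766 higher and 1624 lower. A probe of a region on chromosome 2 from 113880070 to 113887230 on the forward strand (mm9) passed as higher, with a fitted difference of 6.854 (SE 0.115, adjusted p = 1.77e-13), but was above background on 2 of 10 lacZ arrays, so its size and rank were not measured. Another probe of this region had a fitted difference of 4.05 (SE 0.52, above background on 2 lacZ arrays), and a further one, above background on 0 lacZ arrays, also passed as higher. The nearest named probe, of Actc1, lay 6947 bp away and was 8.69 higher. A region on chromosome 9 from 78107225 to 78118850 was 5.30 higher (SE 0.14, above background on 5 lacZ arrays), and a region on chromosome 19 from 60220577 to 60238494 was 3.24 lower on the log2 scale (a difference of -3.24, SE 0.25, above background on 2 MGT arrays).

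Macrophage markers rose in lacZ cultures from day 0 to day 14 (18 of 20, median 2.272), between 2 groups of the same slide, and the list stood out from other genes only at the preset correlation (adjusted p = 0.558 with an estimated correlation). A lower fibroblast share that raises every other cell type is argued against by endothelial markers, whose median was -2.428, unless endothelial cells were lost separately. The mean of the fibroblast identity list was not lower at day 14, at 3.61 and 3.50 on the lacZ arrays against 3.01 and 3.02 on the day 0 arrays. More macrophages in the cultures, or induction of their genes in other cells, was not tested and stays open.

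Interferon response genes were lower with MGT up to day 7 and the difference closed later, by the tests at the preset correlation, while with an estimated correlation the adjusted p = 0.264, 0.161 and 0.278 at days 3, 5 and 7 and 0.188 for the change. The separate slides of the day 14 arrays are argued against as its cause by the median change of 1.055 from day 3 to day 10, where lacZ and MGT share a slide each day. The scaling of the arrays is argued against by the lowest median change over the 4 other scalings, 1.189. An effect of the factors on the response to the virus may remain, as a hypothesis that was not tested. The list showed no rise after the lacZ virus. Its mean was 4.19 and 4.16 on the day 0 arrays, 3.60 and 3.62 on the day 3 lacZ arrays and 2.50 and 1.91 on the day 14 lacZ arrays. No untransduced culture was taken after day 0, so a response to the virus cannot be told apart from time in culture.

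More genes differed at day 14 than at day 10 (8591 against 7105, a ratio of 1.209), but fewer with only the 4 arrays of each comparison (2699 against 3286). The fit over all arrays used 1 spread per gene, while the spread of replicates was unequal. Their median absolute log2 difference was 0.264 in day 14 lacZ, 0.0757 in day 14 MGT, 0.185 in day 10 lacZ and 0.0991 in day 10 MGT. It was 0.0583 in day 3 lacZ. With the spread of each comparison's own 4 arrays the excess at day 14 was absent, so it depended on the spread shared over all arrays. Whether the unequal spread alone did this was not tested. A lower background on the slide of the day 14 MGT arrays is argued against by a ratio of 1.208 among genes above background on every array. The test of the dim second day 14 lacZ array was changed 2 times after its outcome was seen: leaving out that array alone gave 0.9625, which met the condition set for a cause, but leaving out either day 14 MGT array gave 0.9765 and 0.9774, so arrays were made equal, judged at first on the lowest ratio (1.045) and then on the highest (1.086), which leaves it open. With the first day 14 lacZ array left out in its place the ratios were 1.267 and 1.219. A difference between slides cannot be told apart from the vector at day 14, since 0 slides hold both groups.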

How the results depend on the processing

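The scaling by the 75th percentile over detected probes, the fits within slides and day 10 in place of day 14 were chosen only after the results were seen. Of the gene counts under other settings 170 lay within 1.5 times the main count and 14 did not. With a log2 difference of at least 1 also required, the counts were 1460, 2122, 2176, 2142 and 2588 at days 3, 5, 7, 10 and 14, 1985 on average, 1685 for the change over time, and 3411, 5658 and 6204 for lacZ day 3, lacZ day 14 and MGT day 14 against day 0, fewer because the threshold is stricter. With only the arrays of the comparison 3286 genes differed at day 10, 2699 at day 14 and 3294 for the change over time. The same setting gave more genes than the main fit at day 3 (7367) and day 5 (7096), so fewer arrays alone do not account for the drop. Using day 10 in place of day 14, 2861 genes changed. The cause was not tested for either setting. Lists shifted numbered 5 on average, 3 for the change over time and 1 for lacZ day 3 with an estimated correlation, 19 on average and 21 for lacZ day 3 with fry, which does not compare a list with other genes, and 3 for lacZ day 3 with quantile normalization, where the cause was not tested. Single list shifts kept direction and side of the threshold in 539 cases and lost the call in 51, and the median of 2 turned with normexp, skeletal muscle (-0.312) and glial genes (-0.172) for the change over time, where the cause was not tested. Named genes did so in 3600 cases, lost the call in 9 (Gata4, Ucn2, Galntl5, Ush1c and Albfm1) and gained it in 16. Leaving out 1 array gave 3750 to 3986 genes at day 3, 5187 to 5644 at day 5, 5098 to 5747 at day 7, 5333 to 6658 at day 10, 6685 to 9570 at day 14, 11029 to 12338 on average, 3594 to 7305 for the change over time, 8706 to 9133 for lacZ day 3, 11313 to 12873 for lacZ day 14 and 11520 to 11732 for MGT day 14, and 10 to 12, 7 to 9 and 3 to 6 lists, with the lone array assumed to vary like the other groups. The replicate numbers do not pair the samples (correlations of replicate differences from -0.0907 to 0.156, 3 of 55 pairs of groups over 0.1). With the replicate number as a block the counts were 5455, 6822, 6700, 7068 and 8547 per day, 11538 on average, 4928 for the change over time, and 10424, 12426 and 12727 against day 0, with 11, 9 and 6 lists. The median of all genes moved by over 0.1 with normexp, to -0.242 at day 14, -0.192 for the change over time and 0.222 for lacZ day 14, and with no filter on dim probes, which also tests dimmer genes, to -0.221, -0.148 and 0.278, with -0.124 for lacZ day 3 and -0.244 for MGT day 14. The planned slide block was not run, since each group lies on 1 slide. Signal over background limits genes above it on some arrays of a set, whose fitted differences rest in part on signals at background. It also limits genes above it on none, whose differences are bounds that hold for the main settings only.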

Other observations

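The comparison of Mef2c between day 3 and day 14 within each vector was chosen only after the result was seen, and the other values come from planned comparisons. In the averaged comparison of MGT with lacZ, where 63.9% of all genes differed, camera called no shift for the next 3 lists. Of 19 TGF-beta pathway genes 13 fell and 5 rose, of 13 Notch pathway genes 9 fell and 3 rose, and of 20 chromatin regulators 7 fell and 5 rose. Ltbp1, which binds latent TGF-beta, rose by 2.97 (SE 0.05) and Tgfb2 by 1.44 (SE 0.03), the receptor gene Notch3 fell by 1.52 (SE 0.05) and its ligand gene Jag1 by 1.46 (SE 0.03), and Tet1, which oxidises methylated cytosine, rose by 2.25 (SE 0.08), each above background on all 20 arrays. In lacZ cultures from day 0 to day 14 Heyl, a target of Notch signals, rose by 4.41 (SE 0.14) and the fibulin gene Fbln1 by 3.84 (SE 0.11), and Cspg4 fell by 4.19 (SE 0.13).

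The Mef2c level with MGT changed by -2.90 from day 3 to day 14 (SE 0.52, adjusted p = 0.000406 by limma with Benjamini-Hochberg). In lacZ cultures Mef2c was 1.62 higher at day 14 than at day 3 (SE 0.52, adjusted p = 0.0168), which does not show what the cells' own Mef2c gene did in MGT cultures. For both vectors days 3 and 14 lay on different slides, so slide and time cannot be told apart. Both SEs rest on the spread over all 11 groups, among them day 5 lacZ, whose 2 arrays lay apart (SD 1.69). Whether RNA of the vector or of the cells' own gene decreased in MGT cultures was not tested and stays open.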
